A study of Mus musculus with 2 samples.

How the data were processed

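Polyadenylated RNA was measured in 2 sequencing libraries of mouse medullary thymic epithelial cells (mTECs) with high surface MHC class II, 1 library labelled WT and 1 labelled Aire-KO. Per the labels' protocols, the cells came from pools of C57BL/6 mice and were isolated by flow cytometry, RNA was extracted with Trizol, and libraries were made with a stranded mRNA kit. How many mice were pooled, their age and sex, and the targeted allele are not given in the sources used here. With 1 library per genotype, no spread between animals or between libraries can be measured.

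The authors deposited a gene table and an isoform table whose expression values are in FPKM, fragments per kilobase of transcript and per 1000000 fragments. Per the submitters' processing notes, TopHat2 and Cuffdiff were used with genome build mm10. Versions, the annotation release and the scaling between libraries are not given in the sources used here, and the identifiers are RefSeq transcripts. There were 23997 rows of genes and 33295 rows of isoforms. The deposited tables also hold the authors' p-value and q-value for each row, from a comparison of these 2 libraries. Those values compare 2 libraries, not 2 genotypes, and are quoted only as the authors' own. The deposited fold-change column was not used, and ratios were computed from the FPKM values.

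FPKM divides by transcript length and by library total, so a group of abundant genes that differs between libraries shifts all other genes slightly. FPKM values of genes that share reads with near-identical copies depend on how the authors' tool split those reads. In 5 gene rows the authors' tool gave up because of high coverage (status HIDATA), among them Cd74 and Rn45s, and these were treated as missing and not as 0. This departs from the plan to use rows of every status and was chosen after seeing the data. Another 27 gene symbols had been turned into calendar dates, and all 27 were recovered from their position and the RefSeq gene table of assembly GRCm38.p6, the same build as mm10. Of the 23997 row names, 23866 matched that table. Rows that join several symbols, 104 in all, were kept as 1 gene. An exact 0 can be a failed estimate, so a gene is described as listed at 0, with no fold. Of 23884 genes compared, 23846 equalled the sum of their isoforms within 1 percent in both libraries.

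Depth was estimated from the values. For genes with 1 isoform and a transcript of 2000 bp or more, FPKM times effective length fell on whole multiples of 1 step. The low values, up to 5 fragments, numbered 140 in the library labelled WT and 401 in the library labelled Aire-KO. Of these, 75.0% and 80.0% lay within 0.1 of a whole multiple. Chance gives 20% for a step fixed beforehand. Here the step and the effective length were fitted to these same values, so these shares do not test the step. The effective length was the transcript length less 170 bp and 150 bp, respectively. Transcript lengths came from GENCODE release M21 through its RefSeq links. The estimated fragments in 21463 genes were 42970000 and 55610000. The step alone implies 46600000 and 53500000 fragments in all if the authors' tool applied no further scaling. The latter is below the gene total of the same library, so these totals are approximate. A transcript of 2000 bp at 0.5 FPKM then rests on about 42.7 and 49.5 fragments, and a count of 0 fragments allows up to 0.0351 and 0.0303 FPKM (3 counts). Exact conditional binomial 95% intervals of the log2 ratio of FPKM, without a pseudocount, were computed from these fragments for genes whose isoforms are 500 bp or longer. They cover counting error only, since fragments without molecular identifiers are not independent molecules.

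Ratios are log2((FPKM in the library labelled Aire-KO + 0.1)/(FPKM in the library labelled WT + 0.1)), which understates the change of low genes. A gene was called lower or higher at a 2-fold difference on this scale, among genes with a mean of 0.5 FPKM or more. This is a rule of size and not a test. The same rule was used for isoforms. A share shift was a change of 25 percentage points or more in an isoform's share of a gene with at least 5 FPKM in both libraries. The effective isoform number, the exponential of the Shannon entropy of isoform shares, was compared with 10000 random sets of genes within 1.25-fold, matched on FPKM decile and number of isoforms, for genes with 2 or more isoforms. That last limit was set after seeing the data. Clustering along chromosomes was compared with 10000 random placements matched on mean FPKM. For each of 56 gene lists, the median log2 ratio was placed among 10000 random lists of the same size matched on mean FPKM in 20 bins. These percentiles describe these libraries across genes and are not tests of genotype.

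Lists, size rule and the rule for named genes were fixed before the data were examined. The rule names Aire, the 12 lowest and 12 highest ratios at a mean of 2 FPKM or more with both values above 0, and the 5 most expressed genes listed at 0 in each library. It also names all members of the 2 readout lists, up to 4 most expressed and 2 most changed members of the other lists, Raver2 and the 6 largest isoform share shifts. Predicted, small-RNA and mitochondrial names were left out of the ranked parts. Genes outside the rule are said to be so where they appear.

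Alternatives were other pseudocounts (0.01 and 1 FPKM), other filters, centring on the median gene, rescaling to a sum of 1000000, a 4-fold threshold, isoform sums and, added after seeing the data, HIDATA taken as 0, a correction for transcript length and GC content, and a counting interval clear of 0. The steps for lower and higher genes and isoforms, the value of 1 fragment, counting intervals, gene lists, clustering, share shifts, the effective isoform number and the length and GC correction were tested on simulated data. The comparison of lower and higher genes was run on 15910 simulated genes, with counting noise as the only noise. Of the genes given log2 changes of -2, 2, -3 or 3, 100% were recovered, and 0.0318% of unchanged genes were called. No smaller change was simulated, so these shares do not show recovery near the 2-fold threshold. Recovery was not split by expression level, so it cannot be read for weakly expressed genes alone. Of the counting intervals simulated for those 15910 genes, 94.9% held the simulated ratio. For isoform share shifts, run on 2730 genes, 100% of simulated shifts of 40 points were recovered and 0% of unchanged genes were called. This left out the error of splitting reads between isoforms, and no shift nearer to the threshold of 25 points was simulated. Computation used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.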

Results

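Gene expression was profiled in mTECs with high MHC class II, the thymic epithelial cells that display proteins of peripheral tissues to developing T cells. There was 1 library labelled WT and 1 labelled Aire-KO, each from pooled mice. Aire is the transcriptional regulator that drives much of this display. Without the 5 genes that had no estimate, the FPKM values summed to 523609 in the library labelled WT and 551619 in the library labelled Aire-KO, with an estimated 42970000 and 55610000 fragments in genes. In what follows, lower and higher refer to the library labelled Aire-KO relative to the library labelled WT, and paired values give the library labelled WT before the library labelled Aire-KO. No difference has a replicate check. Intervals of the log2 ratio of a gene cover counting error only. Intervals over genes treat genes as independent and cover no spread between animals or libraries.

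The transcript of the targeted gene was not lower in the library labelled Aire-KO. Aire (chromosome 10, 78030022 to 78043610, mm10) stood at 220.6 FPKM in the library labelled WT and 640.2 FPKM in the library labelled Aire-KO, a log2 ratio of 1.54 (95% counting interval 1.51 to 1.56). The 2 most abundant isoforms were both higher, NM_001271549 at 73.6 and 226.3 FPKM and NM_009646 at 68.5 and 196.7 FPKM. Their shares of the gene were 33.4% and 35.4% for the former and 31.1% and 30.7% for the latter. A gene-level FPKM covers the whole transcript and the labels do not state the allele, so these values cannot isolate a deleted part. The transcript level therefore neither bears out nor contradicts the label, and every direction is given by library label.

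The 1st comparison asked which genes differed between the library labelled WT and the library labelled Aire-KO. Lower genes included several typical of peripheral tissues. Ins2, an insulin gene (chromosome 7, 142678656 to 142679726), stood at 72.1 and 0.197 FPKM, and the trefoil peptide gene Tff3 at 400.8 and 5.32 FPKM. Spt1, a salivary protein gene (chromosome 15, 103895855 to 103899312), was at 147.8 FPKM in the library labelled WT and listed at 0 in the library labelled Aire-KO. Among higher genes, Ctla4, an inhibitory receptor best known from T cells (chromosome 1, 60909025 to 60915832), stood at 11.1 and 83.4 FPKM, a log2 ratio of 2.90 (2.81 to 3.01).

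Of 15906 genes with a mean of 0.5 FPKM or more, 3260 were lower, 1128 higher and 11518 neither. Lower genes made up 74.3% of the 4388 changed genes (exact binomial interval over genes 73.0% to 75.6%). At a 4-fold threshold, 1893 genes were lower and 100 higher. The excess was strongest among weakly expressed genes. Of 1557 genes with a mean of 0.5 to 1 FPKM, 806 were lower and 117 higher. Of 1922 genes at 50 FPKM or more, 206 were lower and 151 higher. With a mean of 2 FPKM or more required, 1804 were lower and 876 higher. Of the lower genes, 257 were listed at 0 in the library labelled Aire-KO, and of the higher genes 18 were listed at 0 in the library labelled WT.

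**Figure D1:**
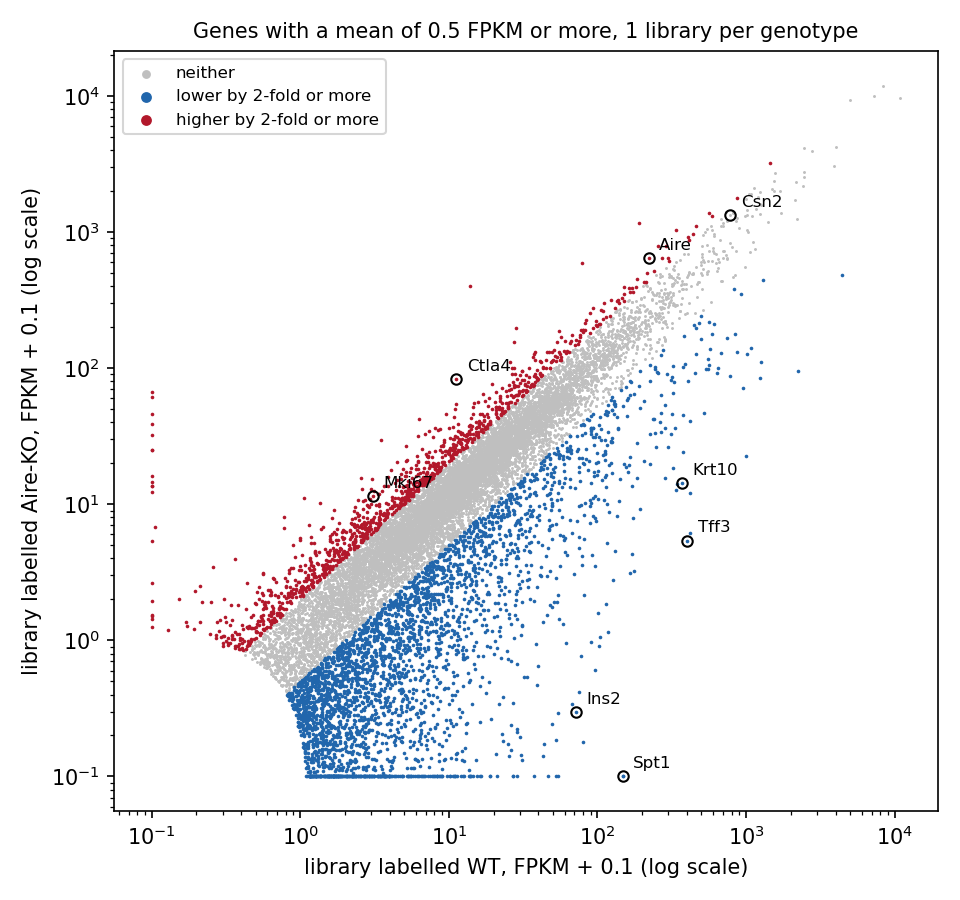
FPKM + 0.1 of each gene with a mean of 0.5 FPKM or more in the library labelled WT (x axis, log scale) and in the library labelled Aire-KO (y axis, log scale), 1 point per gene and 1 library per genotype, with 8 genes circled. The 3260 lower genes (blue) outnumber the 1128 higher genes (red), and Aire lies above the diagonal.

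The lowest ratios with a value in both libraries belonged to Sbpl (79.5 and 0.0784 FPKM), Dcpp1 (42.7 and 0.0413 FPKM), the embryonic globin gene Hba-x (52.1 and 0.0858 FPKM), Prss29 (43.5 and 0.0730 FPKM) and Ins2. They were followed by the mucosal keratin gene Krt13 (30.9 and 0.0323 FPKM), the calcium-binding protein gene Calb2 (30.5 and 0.0439 FPKM) and the pancreatic phospholipase gene Pla2g1b (49.1 and 0.145 FPKM). The hormone genes Ppy (67.4 and 0.238 FPKM) and Gip (54.0 and 0.193 FPKM), Dcpp3 (25.3 and 0.0419 FPKM) and the gastric protease precursor gene Pgc (74.6 and 0.319 FPKM) completed the 12. Besides Spt1, the most expressed genes listed at 0 in the library labelled Aire-KO were the hormone genes Sst (52.7 FPKM) and Oxt (37.4 FPKM), the defensin gene Defb19 (46.3 FPKM) and the odorant-binding protein gene Obp2a (28.7 FPKM). Dcpp1 and Dcpp3 are close copies, and their values depend on how shared reads were split. In the library labelled Aire-KO, Dcpp1 and Dcpp3 rested on 1 estimated fragment each. Sbpl, Hba-x, Krt13, Calb2 and Pla2g1b rested on 3 each, Prss29 on 4 and Gip on 5. Ins2 and Ppy had no fragment estimate. The order among all these genes is therefore not resolved.

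Among the 12 highest ratios were Siglec15, a sialic acid-binding receptor gene (1.255 and 10.1 FPKM), the hexokinase gene Hk3 (1.59 and 9.04 FPKM), the metalloprotease gene Adam19 (6.12 and 31.9 FPKM) and S100a2 (2.44 and 15.5 FPKM). The pituitary hormone subunit gene Lhb stood at 0.791 and 4.90 FPKM, Defb33 at 0.266 and 3.89 FPKM, Lincrna-cox2 at 1.04 and 6.89 FPKM and AY761185 at 5.04 and 26.6 FPKM. Lars2, the mitochondrial leucyl-tRNA synthetase gene, stood at 191.6 and 1173 FPKM. Values of AY761185, Defb33 and S100a2 are uncertain, because these transcripts of 448, 424 and 315 bp had no fragment estimate or counting interval. Which RNAs the reads counted for Lars2 came from was not examined. Values of Rps15a-ps6 (6.24 and 42.2 FPKM) and Eif3j2 (0.00484 and 6.71 FPKM) are also uncertain. The former is a pseudogene, and the row that joins Eif3j1 and Eif3j2 went the other way, 3.14 and 0.0319 FPKM. Of the 18 genes listed at 0 in the library labelled WT at a mean of 0.5 FPKM or more, 17 had predicted or small-RNA names, up to 66.3 FPKM for Mir1291 (named after its value was seen), and short RNAs are poorly measured by FPKM. With such names left out, and without a minimum, the highest were Hist1h2bm (1.42 FPKM), Arl9 (0.874 FPKM), Rbm14-rbm4 (0.707 FPKM), Hist1h2bp (0.581 FPKM) and Vpreb1 (0.463 FPKM).

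The authors' deposited table called 70 genes, all 70 lower, of which 59 were listed at 0 in the library labelled Aire-KO. In the authors' deposited table the called genes with a value in both libraries numbered 11, among them Krt10, Gp2, Bpifa1 and Apoa4 with q of 0.0155, the smallest in the table. The authors' deposited table gave q of 0.790 for Ins2, 0.125 for Ctla4 and 0.708 for Aire. Those q values compare 2 libraries and not 2 genotypes.

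The 2nd comparison asked whether genes commonly used as readouts of Aire differed. Of 12 Aire-dependent readouts, 10 reached the mean of 0.5 FPKM, and 9 of these were lower. The median log2 ratio was -5.04, below all 10000 random lists. S100a8, a neutrophil calcium-binding protein gene, stood at 781.5 and 87.0 FPKM, the chemokine gene Xcl1 at 28.8 and 0.111 FPKM and the plasma protein gene Itih3 at 3.13 and 0.0976 FPKM. Mup4, a urinary protein gene (5.78 FPKM), and Bpifb9a (1.08 FPKM) were listed at 0 in the library labelled Aire-KO, and Bpifb9b stood at 2.28 and 0.0295 FPKM. The exception was the milk protein gene Csn2 (chromosome 5, 87692619 to 87699429), at 784.4 and 1336 FPKM, a log2 ratio of 0.77 (0.75 to 0.79). Muc6 (0.399 and 0.0161 FPKM) and Rbp3 (0.157 FPKM and listed at 0) were below the minimum.

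A list that pools readouts regarded as independent of Aire with readouts linked to the transcription factor Fezf2 was also mostly lower. The 2 kinds were not counted apart, so the list does not show that Aire-independent readouts were lower as a class. Of 10 measured, 7 were lower, 1 higher and 2 neither, with a median log2 ratio of -1.70 (0.0300th percentile). Lower genes included Krt10, a keratin of differentiated epidermis (372.5 and 14.3 FPKM), the apolipoprotein gene Apoc3 (227.1 and 32.5 FPKM), Ttr (71.0 and 13.0 FPKM), Fabp9 (328.3 and 79.6 FPKM), Resp18 (561.2 and 219.6 FPKM), Calb1 (7.18 and 2.91 FPKM) and Apob (3.27 and 0.287 FPKM). The acute-phase gene Crp (14.4 and 11.7 FPKM) and Gad1, a glutamate decarboxylase gene (5.47 and 3.44 FPKM), were neither. Maoa, the monoamine oxidase A gene, was higher (10.6 and 23.5 FPKM). Fezf2 dependence was not measured here.

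The 3rd comparison took the tissue lists. Over 15 tissue lists, 266 different genes were measured, of which 209 were lower, 7 higher and 50 neither. That is 78.6% lower, against 20.5% of all measured genes, and all 15 list medians lay below the 2.5th percentile of random lists. Most measured digestive genes were lower. In the exocrine pancreas list 20 of 22 genes were lower (median log2 -4.03), including the antimicrobial lectin gene Reg3g (4426 and 487.4 FPKM) and the trypsin inhibitor gene Spink3 (1237 and 84.8 FPKM). In the intestine list 23 of 26 were lower (-3.45), including Apoa4 (520.1 and 46.5 FPKM), whereas the transcription factor gene Cdx1 stood at 140.3 and 253.2 FPKM. In the stomach list 13 of 14 were lower (-4.25), including Tff1 (175.7 and 3.12 FPKM).

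Most measured gland and hormone genes were also lower. Of 20 endocrine hormone genes 16 were lower and 1 higher (median log2 -4.44), with the gut hormone gene Pyy at 114.9 and 1.74 FPKM and Iapp at 192.2 and 9.21 FPKM. Of 14 salivary and lacrimal genes 12 were lower (-4.84), but the peroxidase gene Lpo stood at 138.7 and 174.3 FPKM. Of 8 mammary genes 6 were lower (-2.93), among them the iron-binding protein gene Ltf (61.2 and 0.854 FPKM), and of 15 male reproductive genes 11 (-2.68). In the liver list 19 of 25 were lower (-3.22), with the albumin gene Alb at 11.2 and 0.0492 FPKM. In the lung list 13 of 15 were lower (-3.73), with Scgb1a1, a club cell secretory gene, at 286.5 and 15.5 FPKM. In the kidney list 6 of 8 were lower (-2.62), and in the thyroid and adrenal list 6 of 9 (-1.82, 2.07th percentile).

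Epidermal and structural genes followed. In the cornified epidermis list 24 of 26 genes were lower and 1 higher (median log2 -3.21), with Krtdap at 1087 and 140.2 FPKM. In the lens and retina list 17 of 21 were lower and 1 higher (-2.52), with the lens crystallin gene Cryaa at 30.1 and 0.0964 FPKM. Of 25 muscle genes 16 were lower and 2 higher (-1.31), with the atrial hormone gene Nppa at 26.0 and 0.0560 FPKM. The brain list had the median nearest to 0 among the tissue lists, with 9 of 21 lower and 2 higher (-0.65, 1.56th percentile). There the synapsin gene Syn2 stood at 11.1 and 54.5 FPKM and the synaptotagmin gene Syt1 at 82.2 and 128.1 FPKM. Gene families, in which reads can be shared between paralogs, differed in direction. All 33 small proline-rich and late cornified envelope genes were lower, as were 34 of 42 keratins, 38 of 53 cytochrome P450 genes, 13 of 14 kallikrein 1-related genes and 23 of 28 defensins. In contrast, 27 of 75 ribosomal protein genes were higher and 1 lower, and none of 44 proteasome genes passed the 2-fold rule.

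**Figure D2:**
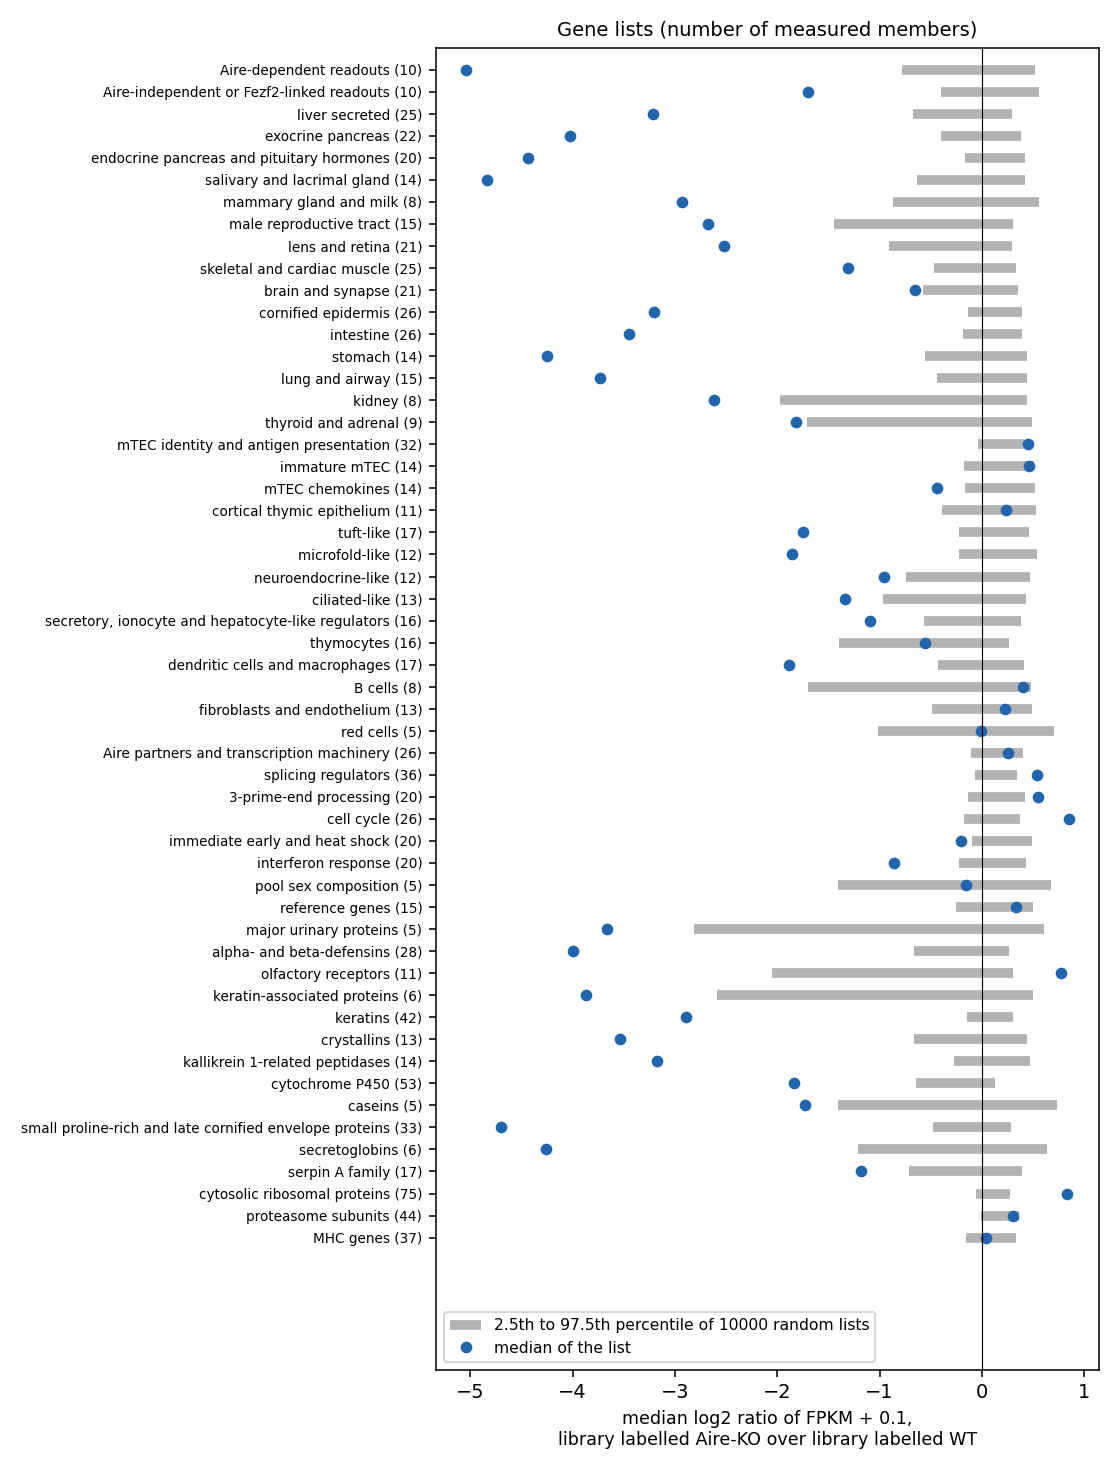
Median log2 ratio of each gene list (blue points, x axis, FPKM + 0.1, library labelled Aire-KO over library labelled WT), with the number of measured members in parentheses and grey bars for the central 95% of 10000 random lists. All 15 tissue lists lie left of their bars, while the cell cycle list (0.85) and the ribosomal protein list (0.83) lie to the right.

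The 4th comparison concerned mTEC identity. The MHC class II genes H2-Aa (8398 and 11948 FPKM) and H2-Ab1 (7283 and 10067 FPKM) and the epithelial keratin gene Krt18 (1679 and 1990 FPKM) were high in both libraries and neither lower nor higher, whereas the keratin gene Krt19 was lower (184.4 and 15.6 FPKM). Of 32 identity genes 3 were lower, 4 higher and 25 neither, with a median log2 ratio of 0.45 (98.8th percentile). Besides Krt19, the interferon regulator gene Irf7 (118.4 and 33.8 FPKM) was among the lower genes. Cd74, the invariant chain gene, had no estimate in the library labelled Aire-KO. Of 14 immature mTEC genes 3 were lower and 2 higher (0.46, 95.5th percentile), with Krt15 at 47.8 and 6.80 FPKM. Of 14 chemokine genes 5 were lower and none higher (-0.44, 0.140th percentile), with Ccl20 at 375.5 and 45.3 FPKM and Ccl5 at 569.8 and 139.1 FPKM, while Ccl25 stood at 546.4 and 809.2 FPKM.

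Marker lists of mimetic cells, mTECs that resemble peripheral cell types, were lower as groups. Of 17 tuft-like genes 15 were lower (median log2 -1.75, below all 10000 random lists), including the taste channel gene Trpm5 (57.1 and 10.8 FPKM) and Avil (122.4 and 28.4 FPKM). Of 12 microfold-like genes 7 were lower (-1.85), with Gp2 at 375.3 and 24.0 FPKM, whereas the regulator gene Spib stood at 180.8 and 262.5 FPKM. Of 13 ciliated-like genes 10 were lower and 1 higher (-1.34), with the dynein gene Dynlrb2 at 22.3 and 0.642 FPKM and the regulator gene Foxj1 at 36.1 and 43.0 FPKM. Of 12 neuroendocrine-like genes 6 were lower and 1 higher (-0.96), with Chga at 45.5 and 16.6 FPKM and the regulator gene Insm1 at 53.4 and 120.5 FPKM. Of 16 secretory, ionocyte and hepatocyte-like regulators 8 were lower and 1 higher (-1.09), with the ionocyte regulator gene Foxi1 at 6.999 and 0.0845 FPKM and Nkx6-2 at 20.5 and 66.9 FPKM.

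Markers of other cells that a thymic sort could hold differed in both directions. Of 17 dendritic cell and macrophage genes 12 were lower and none higher (median log2 -1.89, below all 10000 random lists), with Itgam at 9.40 and 0.614 FPKM, but Lyz2 stood at 675.5 and 436.4 FPKM and Fcer1g at 60.2 and 87.2 FPKM. Of 16 thymocyte genes 6 were lower and 2 higher (-0.56, 29.6th percentile), with Cd3g at 7.63 and 2.72 FPKM and Tcf7 at 21.6 and 51.7 FPKM. Medians of the cortical epithelium (0.23), B cell (0.40), fibroblast and endothelium (0.23) and red cell (-0.02) lists lay within the range of random lists.

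The 5th comparison concerned isoforms. The splicing regulator gene Raver2 (chromosome 4, 101069038 to 101152370) stood at 12.3 and 24.3 FPKM, a log2 ratio of 0.97 (0.91 to 1.05), just under the 2-fold rule. Of 36 splicing regulators 1 was lower, the neuronal factor gene Rbfox3 (2.24 and 0.338 FPKM), and 1 higher, Hnrnpa1 (11.9 and 24.4 FPKM). Their median of 0.54 lay above all 10000 random lists. Of 20 genes of 3-prime-end processing none passed the 2-fold rule in either direction, with a median of 0.55 (99.8th percentile). Cpsf6 stood at 9.03 and 17.4 FPKM.

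Of 19772 isoforms with a mean of 0.5 FPKM or more, 3981 were lower and 2017 higher. Among 2499 genes with 2 or more isoforms and at least 5 FPKM in both libraries, 142 (5.68%) had a share shift of 25 percentage points or more. The count was 437 at 15 points and 38 at 40 points, and it was 417 with 1 FPKM and 25 with 20 FPKM required in both libraries. Of those 142 genes, 16 were lower and 8 higher as genes, against 116 lower and 153 higher of all 2499. In Acp1, a phosphatase gene, NM_001110239 made up 0.723% of the gene in the library labelled WT and 98.5% in the library labelled Aire-KO. In Commd6, NM_001033132 was listed at 0 and then made up 94.8%. In the guanylate cyclase gene Gucy2c, NM_145067 was listed at 0 and then made up 88.3%. NM_001001327 of Vkorc1l1 made up 0.0214% and 75.1%, NM_001253354 of Fam214b 0.0708% and 73.1%, and NM_011847 of the chaperone gene Dnajb6 0.285% and 72.4%. These shares carry the error of splitting reads between overlapping isoforms, which was not measured. In the library labelled WT, the median effective isoform number of 678 lower genes was 1.56, against 1.61 in matched random sets (95% of sets between 1.53 and 1.66). This difference of -0.046 was within the range of random sets (18.2nd percentile), as it was at a mean of 2 FPKM or more (-0.038, 9.12th percentile) and for 4-fold lower genes (-0.093, 3.54th percentile). It was -0.415, below all 10000 random sets, when matching and shares were both taken from the library labelled Aire-KO, which changes 2 choices at once.

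Lower genes were neighbours more often than random placement gave. The next measured gene was also lower for 37.3% of the 3260 lower genes, against a median of 21.2% and a maximum of 23.5% over 10000 placements. With 1 gene kept per name stem and chromosome, the share was 28.2% against 18.7%. This removes tandem paralogs that share a stem and keeps those with different stems. How many tandem paralogs remained was not measured. The longest run held 47 lower genes from S100a7a to Gm4858 on chromosome 3 (90651925 to 93075505, mm10). It includes the Sprr and Lce genes of the epidermal barrier and S100a8. Runs of 14 genes lay on chromosome 14, from Cma1 to Atp12a, and on chromosome 15, from Psca to 2010109I03Rik. The run on chromosome 14 holds mast cell protease and granzyme genes. The genes at the ends of runs were named after their values were seen.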

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

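Alternatives chosen after the data were seen were HIDATA taken as 0, the length and GC correction, and the counting interval. Lower genes outnumbered higher genes under all alternatives run. With a pseudocount of 1 FPKM, 701 genes were higher and 77.5% of changed genes were lower. With no filter 5180 genes were lower (79.3%), at a mean of 0.1 FPKM or more the share was 78.8%, and at 2 FPKM or more 1804 were lower (67.3%). At 4-fold 1893 were lower and 100 higher (94.98%). The share was 79.5% after centring on the median gene, which shifts log2 ratios by 0.09, 79.8% after rescaling and 75.8% without predicted names. The Aire log2 ratio was 1.44 after centring and 1.46 after rescaling. Isoform counts were 1230 higher with a pseudocount of 1 FPKM, 6706 lower with no filter, 6156 lower at 0.1 FPKM, and 2046 lower and 1298 higher at 2 FPKM. Isoform share shifts numbered 437 at 15 points, 38 at 40 points, 417 at 1 FPKM and 25 at 20 FPKM. The difference in effective isoform number was -0.093 at 4-fold and -0.415 with matching and shares both from the library labelled Aire-KO (below all random sets), against -0.046. It was 0.00 with single-isoform genes kept, a limit also set after the data were seen. Neighbours were lower for 28.2% with 1 gene per stem (random median 18.7%) and for 78.7% within 3 positions (random median 74.9%). The olfactory receptor median reversed to -1.62 at 0.1 FPKM and -0.052 after rescaling. These settings differ in the genes admitted, threshold, pseudocount, scale, neighbour distance or matching, and what caused each difference was not tested. Of 43 lists that stood apart, 42 kept their direction under all alternatives run. Some of the lists share genes, so they are not independent of each other. The minimum of 0.5 FPKM nearly ensures that a 2-fold difference has a counting interval clear of 0, so that alternative is no check on depth. Depth limits genes listed at 0. For a 2000 bp transcript, a 0 allows up to 0.0351 FPKM in the library labelled WT and 0.0303 FPKM in the library labelled Aire-KO. Shorter transcripts allow more. All 5 most expressed genes listed at 0 in the library labelled Aire-KO were shorter, such as Oxt (537 bp) and Spt1 (639 bp).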

Other observations

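Cell cycle genes and cytosolic ribosomal protein genes were higher as groups in the library labelled Aire-KO, although most members did not pass the 2-fold rule. Of 26 cell cycle genes 9 were higher, 17 neither and none lower, with a median log2 ratio of 0.85, above all 10000 random lists. The proliferation marker gene Mki67 stood at 3.01 and 11.3 FPKM (library labelled WT, then library labelled Aire-KO), the kinesin gene Cenpe at 0.791 and 3.31 FPKM and the cyclin gene Ccnb2 at 11.6 and 29.9 FPKM, while Pcna was at 34.2 and 36.5 FPKM. Of 75 cytosolic ribosomal protein genes 27 were higher, 47 neither and 1 lower (median 0.83, above all 10000 random lists). Among 15 reference genes 3 were higher and none lower (0.34, 86.9th percentile), among them the translation factor gene Eef1a1 (1459 and 3200 FPKM). Of 26 genes for Aire partners and transcription machinery 4 were higher and none lower (0.25, 79.1st percentile), among them Sirt1, a deacetylase gene (73.3 and 149.7 FPKM), and Top1, a topoisomerase gene (14.3 and 32.8 FPKM). None of 44 proteasome genes passed the 2-fold rule (0.30, 91.4th percentile).

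Interferon response genes were lower as a group. Of 20 genes 10 were lower and 1 higher (median -0.87, below all 10000 random lists), including the antiviral gene Rsad2 (7.07 and 1.16 FPKM), while the chemokine gene Cxcl10 stood at 563.4 and 732.9 FPKM. Dendritic cell and macrophage markers were also lower as a group (12 of 17, median -1.89). Of 20 immediate early and heat shock genes 1 was lower, Ier3 (65.4 and 31.6 FPKM), with a median of -0.20 (0.410th percentile). Of 37 measured MHC genes 10 were lower and 3 higher (0.04). Of 11 measured olfactory receptor genes 5 were higher and 3 lower, with a median of 0.77 that turned to -1.62 at a minimum mean of 0.1 FPKM and to -0.052 after rescaling to a sum of 1000000. Lower genes numbered 5 of 5 major urinary proteins, 6 of 6 keratin-associated proteins and 6 of 6 secretoglobins. Further lower genes were 10 of 13 crystallins, 3 of 5 caseins and 10 of 17 serpin A genes. Another list also held 5 of the measured secretoglobins, 11 of the crystallins and 5 of the caseins. The same held for 1 major urinary protein, 2 serpin A genes and no keratin-associated protein. These counts are therefore not independent of the other lists. The 1 measured vomeronasal receptor gene, Vmn2r29, stood at 0.703 and 0.330 FPKM, and 0 mitochondrially encoded genes were in the table. The list on the sex mix of the pools had 5 measured genes, 1 higher and 4 neither. Xist, the X-inactivation RNA, was higher (10.7 and 30.1 FPKM). The Y-linked genes stood at 6.36 and 6.18 FPKM (Ddx3y), 16.9 and 11.9 FPKM (Eif2s3y), 1.89 and 1.16 FPKM (Kdm5d) and 3.43 and 3.07 FPKM (Uty). A difference in sex mix between the pools was not tested and cannot be separated from genotype.

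All tests of explanations below were chosen after the results were seen. The 1st pattern is the excess of lower genes. Fragments of the library labelled Aire-KO were estimated at 129.4% of those of the library labelled WT from genes. From the value of 1 fragment the estimate was 114.7%. These values argue against fewer sequenced fragments as the cause, but both rest on the same fitted step. They do not reach a library with fewer distinct molecules, since fragments without molecular identifiers are not independent molecules. A scaling that made all genes lower would put the median gene below 0. Among genes with a mean of 1 FPKM or more, it lay at 0.09 (95% rank interval over 14349 genes 0.080 to 0.106). By level, medians ran from -1.06 at 0.5 to 1 FPKM to 0.19 at 50 FPKM or more. A scale common to all genes would not change sign with level. After the correction for transcript length and GC content, lower genes made up 75.2% of changed genes. Its trend was fitted on genes with a mean of 10 FPKM or more and a difference under 2-fold. The 75.2% argues against such a trend as the whole cause. It does not reach a bias confined to weakly expressed genes, where the excess was strongest. Fewer mimetic cells, which would lower nearly all of their markers, remain open, because 46 of 70 members of the mimetic lists were lower while Insm1, Nkx6-2 and Rsph4a (the last named after its value was seen) were higher, and bulk libraries give no cell shares. An effect of the genotype remains open and cannot be separated from a difference between 2 pools.

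The 2nd pattern is the higher Aire transcript in the library labelled Aire-KO. An exchange of the 2 labels would put the Aire-dependent readouts higher there, and 9 of 10 were lower. A larger share of mature mTECs would raise the identity list over the immature list, whose medians were 0.45 and 0.46. With genes of both lists left out the difference was -0.04 (95% bootstrap interval over genes -0.538 to 1.457), which leaves this open. A targeted allele that still gives a transcript may also account for it, and the labels do not state the allele, so this was not tested.

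The 3rd pattern is the higher median of the ribosomal protein genes. Length or GC bias is argued against by a median of 0.91 over 73 genes after the correction. Centring on the median gene takes the same 0.09 from all genes, so the median of 0.74 it leaves is no test of scaling. A scale common to all genes would raise random lists of matched expression alike. Their median was 0.11, against 0.83 for the ribosomal protein genes, which argues against such a scale as the whole cause. Reads moved from listed pseudogenes would leave those lower, and none of the 5 measured was, with a sum at 176% of that in the library labelled WT. Copies outside the authors' annotation were not measured and remain open, and some ribosomal protein genes had implausibly low values, such as Rpl28 at 0.206 and 1.92 FPKM. An effect of the genotype was not tested and cannot be separated from a difference between 2 pools.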
